A study of Homo sapiens with 18 samples.

How the data were processed

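Total RNA of the human myeloma line MM1.S was measured on 18 Agilent 4x44K arrays, 3 for each of 6 groups: untreated, 12, 24 or 36 h of the CDK4 and CDK6 inhibitor PD0332991 (PD), and 4 or 18 h of release after 24 h of PD. Per the labels' protocols, total RNA was amplified and labelled with Cy3 as cRNA, and each array held 1 sample, with no pooling of replicates. Groups were taken from the labels, and slide and scan day from the file headers.

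The deposited processed signals are intensities that Agilent Feature Extraction (version 10.5.1.1 per the file headers, 9.1 per the submitters' processing notes) had background-subtracted and detrended within each array, with no normalization between arrays. The deposited median signals and local backgrounds are raw pixel intensities, per the file headers. The other columns used, deposited per the file headers as 0 or 1 flags for each spot, mark signals well above background, saturation and non-uniform or deviating spots. The authors' matrix holds log2 values that were deposited with each probe centred to a median of 0 over the arrays. They followed the log2 processed signal of the same array with r of 0.972 to 0.996 and slopes of 0.953 to 1.01, with an offset for each array of unstated origin (column medians -0.277 to 0.271).

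From the files, each array's 75th percentile of the log2 processed signal over non-control probes was subtracted. A spot marked as deviating was removed, spots of the same probe were averaged, and the 622 probes left with no value on an array were dropped. Of 41000 non-control probes on 43376 spots, 23958 had an accession that the RefSeq table of assembly GRCh38.p14 pairs with a gene symbol, 0 had several, and 17042 had none and were left out of the tests. The array's own annotation is of an older assembly (hg18), so no coordinates are given. A probe was kept when it was well above background on all 3 arrays of at least 1 group (37860 probes), and the probe with the highest mean stood for its gene, which left 15814 of 16557 genes, 5764 of the 16557 with more than 1 probe. No spot was saturated. Between 70.9 and 98.2% of the probes of an array were well above background, which limits what can be said of dim genes, mostly on slide 4. The median SD of a gene within a group was 0.134 to 0.272 on the log2 scale.

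One limma fit (version 3.58.1, R 4.3.3) of all 18 arrays with 6 group means, eBayes moderation and Benjamini-Hochberg adjustment gave the 7 comparisons, and changed means an adjusted p under 0.05. The 40 gene lists were fixed before the data were examined, and each was tested with camera at its preset correlation of 0.01, adjusted over the 40 lists. Camera with an estimated correlation and fry, a rotation test, were the alternatives. A list's genes were also counted with the p-values adjusted over that list alone. For a gene well above background on no array of 1 group, that group's levels were raised to each array's lowest signal well above background where they lay below it, and the fold was given as "at least". The groups, the comparisons, the scaling, the filter, the tests and the first set of alternatives were chosen before the data were examined. Named genes are the 8 largest changes in each direction among genes with an adjusted p under 0.05 that were well above background on all 6 arrays and whose values did not overlap between the groups (the largest changes are meant among these), up to 3 bounded genes a direction, a fixed set of core genes, and up to 4 members of each list that changed in its camera direction, by lowest p. Of the genes this rule names, 2 are not reported here, and they stay in the counts and list tests.

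The labels give the groups the same replicate numbers. Deviations from the group means of arrays with the same number correlated at 0.370 to 0.820 for 12 h of PD and untreated cells, 0.362 to 0.686 for 24 h and 0.258 to 0.631 for 36 h. For 4 h of release and 24 h of PD they correlated at 0.175 to 0.511, for 18 h of release at 0.327 to 0.516 and, against untreated cells, at 0.243 to 0.659. By this check the numbers were taken to pair the arrays in these 6 comparisons. Arrays with different numbers were not compared. Replicate 1 of every group was scanned on day 1 and replicates 2 and 3 on day 2. The values therefore do not tell pairing by number from scan day or slide, and the labels name no shared culture. The main fit was left unpaired. Results with the replicate number as a block are given where they change a call.

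Alternatives were other scalings (quantile, median, the 75th percentile over probes well above background on all arrays, the authors' matrix), normexp on the median signals, no filter or a stricter one, the mean of a gene's probes, a variance trend with robust moderation, and only the 6 arrays compared. Slide as a fixed or random block (correlation 0.552), the replicate number or scan day as a block, arrays left out in turn or by slide, and probes without a gene name were also tried. The shares of overlapping calls are set beside those of independent lists and of 20 simulations of unchanged groups against the same untreated arrays, which gave at most 1 call at 24 h and none at 18 h of release and so set no bound on shared calls. The fit was tested on simulated data with known changes in 50 genes per size: it recovered 30, 66, 74 and 92% of the genes changed 1.5-, 2-, 3- and 4-fold, and 4.38% of its 137 calls were false. A list raised by 0.5 passed camera there, and 0 of 39 lists sharing no gene with it passed. The simulated genes were drawn independently and without slide signal. Of the 15814 genes 15614 were left unchanged there, while the real comparisons called 701 to 5038 genes. An adjusted p depends on how many genes change, so the recovery rates hold for the simulated share only. These results therefore do not show how the fit or camera behaves where genes are correlated, slides differ or many genes change. Tables and figures were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.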

Results

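Gene expression was measured in MM1.S, an established human multiple myeloma cell line (multiple myeloma is a cancer of plasma cells), on 18 1-colour Agilent arrays of total RNA. PD0332991 (PD) is a small molecule that inhibits CDK4 and CDK6, the kinases that move cells from G1 towards S phase by phosphorylating RB. The 6 groups held 3 arrays each: untreated cells, cells given 0.25 uM PD for 12, 24 or 36 h, and cells released for 4 or 18 h after 24 h of PD. Levels are log2 signals relative to the array's 75th percentile, as mean ± SD with n = 3, and changes are differences of these means. The share of probes well above background ran from 91.5 to 98.2%, except on the 4 arrays of slide 4, where it was 70.9 to 86.6%. Arrays of a group correlated at 0.975 to 0.998 over genes, and the median SD of a gene within a group was 0.134 to 0.272. The labels name 3 independent RNA isolations a group and say nothing on separate cultures, so the p-values measure the spread between these isolations, which may be technical.

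The arrays lay on 5 slides and were scanned on 2 days, replicate 1 of every group on day 1 and replicates 2 and 3 on day 2. The untreated and 12 h arrays lay on slides 1 to 3, the 24 h arrays on slides 1 and 3, and the 36 h arrays on slides 1, 2 and 4. The 4 h release arrays lay on slides 2, 4 and 5 and the 18 h release arrays on slides 4 and 5, so no release array shared a slide with a 24 h array. The first principal component (40% of the variance) ran from the untreated and 18 h release arrays to the 24 h and 36 h arrays, and the second (27.6%) followed scan day and slide.

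**Figure D1:**
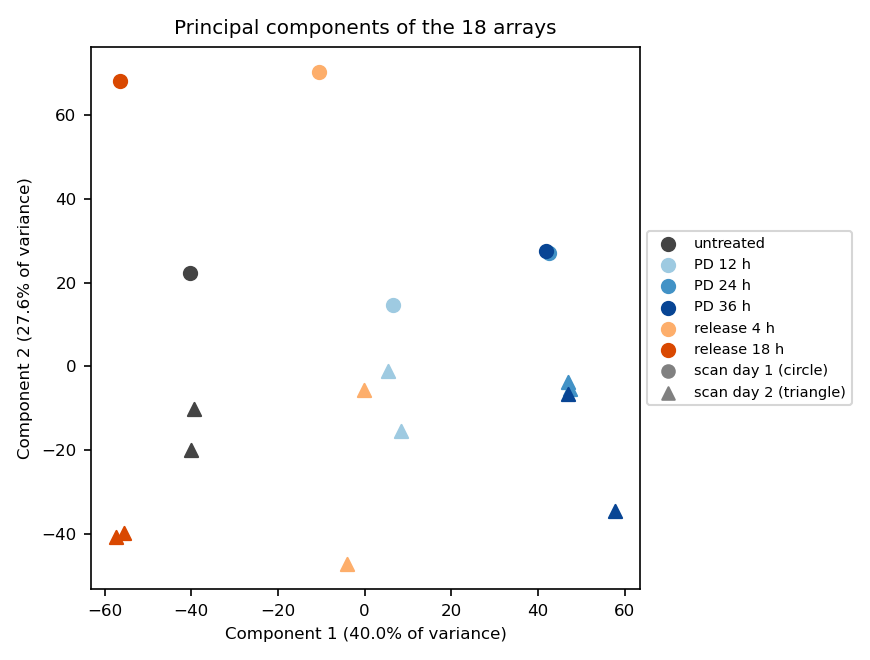
Component scores of the 18 arrays over the tested genes, with colour for the group and marker shape for the scan day (x axis, component 1, 40% of the variance; y axis, component 2, 27.6%). The 24 h and 36 h arrays lie at the right, the untreated and 18 h release arrays at the left, and the day 1 arrays lie above the day 2 arrays of their group.

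After 12 h of PD genes of S phase entry and DNA replication had fallen together, against untreated cells. UHRF1, which maintains DNA methylation behind the replication fork, had the largest fall, from 1.26 ± 0.09 to -3.30 ± 0.11 (23.7-fold; limma adjusted p = 1.44e-11). It was followed by FAM111B, a protease linked to replication (-4.56), CDCA7, a MYC- and E2F-responsive gene (-4.19), and DTL, which targets licensing factors for destruction (-4.07). Of the 29 tested E2F and G1/S regulators 28 fell, also 28 adjusted over the list alone (median -2.12, camera adjusted p = 2.59e-47). They included E2F1 (-3.14), the histone chaperone subunit CHAF1B (-3.19) and CDK2 (-2.90). Of 40 DNA replication genes 38 fell (39 adjusted over the list alone, median -2.05, camera adjusted p = 6.77e-60). The helicase subunits CDC45 and MCM6 changed by -3.48 and -3.19 and the origin licensing factor CDC6 by -3.34.

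Mitotic genes had moved less by 12 h. Of 49 G2/M genes 33 fell (37 adjusted over the list alone), with a median of -0.86 (camera adjusted p = 1.37e-22). The kinesin KIF11 fell by 1.21 and FOXM1, a transcription factor of mitotic genes, by 1.42 on the log2 scale. The changes of the mitotic regulators CCNB1 (-0.12), CDC20 (-0.34) and PLK1 (-0.41) did not pass limma's test (adjusted p = 0.583, 0.218 and 0.281), that of PLK1 only with slide or the replicate number as a block (adjusted p = 0.00941 and 0.0212). Homologous recombination and Fanconi genes fell in 26 of 29 cases and rose in 0 (26 and 1 adjusted over the list alone), with the Fanconi complex subunit FANCI at -1.85 (camera adjusted p = 5.70e-32). Mismatch and base excision repair genes fell in 9 of 15 cases and rose in 1 (10 and 1 adjusted over the list alone, camera adjusted p = 2.85e-07), with the uracil glycosylase UNG at -2.67. Epigenetic regulators linked to the cell cycle fell in 13 of 19 cases and rose in 1 (16 and 1 adjusted over the list alone, camera adjusted p = 3.63e-12), as with the histone methyltransferase EZH2 (-1.65). Nuclear envelope genes fell in 13 of 22 cases (16 adjusted over the list alone, camera adjusted p = 4.53e-10), as with lamin B1 (LMNB1, -1.96).

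Cholesterol and fatty acid synthesis genes were also lower at 12 h. Of 23 cholesterol synthesis genes 11 fell and 0 rose (19 and 1 adjusted over the list alone, median -0.60, camera adjusted p = 5.11e-10). INSIG1, the sterol-responsive regulator, changed by -1.38 and the isomerase IDI1 by -0.85. Of 13 fatty acid synthesis genes 7 fell and 1 rose, the same numbers adjusted over the list alone, with the desaturases FADS1 and SCD at -1.86 and -1.94 (camera adjusted p = 3.04e-04). Of 23 ATF4 stress response genes 10 fell and 3 rose (11 and 3 adjusted over the list alone, camera adjusted p = 1.73e-04), with PSAT1 and PHGDH of serine synthesis at -1.45 and -1.75.

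Genes that rose were led by IFIT1, an interferon-induced antiviral protein, from -2.47 ± 0.06 to -0.35 ± 0.04 (4.36-fold; limma adjusted p = 4.65e-09), BBS12, a chaperonin-like ciliary protein (3.99-fold), and TMEM140 (1.96). In the quiescence and FOXO-linked list 12 of 26 genes rose and 2 fell (12 and 3 adjusted over the list alone, median 0.43, camera adjusted p = 1.19e-05), with KLHL24 at 1.21 and YPEL5 at 1.09. Of 21 plasma cell identity genes 5 rose, as many adjusted over the list alone (camera adjusted p = 6.34e-04, adjusted p = 0.162 with an estimated correlation). The costimulatory receptor CD28 rose by 0.70 and PRDM1, the repressor that drives plasma cell differentiation, by 0.47. IRF4, the transcription factor that myeloma cells depend on, rose by 0.52 (limma adjusted p = 0.00505). Its call ended with the authors' matrix values (adjusted p = 0.0506) and with the mean of all its probes (adjusted p = 0.123). The interferon response list had 15 of 31 genes higher and 3 lower, the same numbers adjusted over the list alone (camera adjusted p = 5.42e-04, adjusted p = 0.0857 with an estimated correlation). Among anti-apoptotic BCL2 family genes 3 of 6 rose, as many adjusted over the list alone, BCL2 by 0.97 and MCL1 by 0.54 (camera adjusted p = 0.0117). In the pro-apoptotic list 1 of 10 genes fell, also 1 adjusted over the list alone (camera adjusted p = 0.146). This was PMAIP1, which encodes NOXA, with a change of -2.41 (limma adjusted p = 7.96e-08).

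In limma's test 2717 of 15814 genes changed at 12 h, 1251 higher and 1466 lower, of which 644 changed at least 2-fold. On the authors' matrix values the split was 494 higher and 1344 lower. Of the 40 lists 21 passed camera and 12 also with an estimated correlation. With slide as a block the count was 4195. The medians of the E2F list were -2.18, -2.20 and -1.91 within slides 1, 2 and 3, beside -2.12 with the block. Those of the G2/M list were -0.80, -0.87 and -0.81, beside -0.86. The sign within each of these slides was that of the pooled change for 100% of the called genes. These genes were called on the same arrays, so the shared sign follows largely from the call.

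After 24 h of PD the mitotic programme had fallen as well. SPC25, a kinetochore subunit, fell from 2.11 ± 0.03 to -4.77 ± 0.10 (118-fold; limma adjusted p = 2.93e-14). Next came the kinesin KIFC1 (-6.46), the mitotic kinase PBK (-6.40), the ribonucleotide reductase subunit RRM2 (-6.40) and the chromosomal passenger kinase AURKB (-6.31). All 49 G2/M genes fell, also adjusted over the list alone (median -4.46, camera adjusted p = 3.54e-71), with CDK1 at -5.83. Of the 29 E2F and G1/S regulators 28 and of the 40 replication genes 39 fell, the same numbers adjusted over each list alone (medians -3.07 and -2.40; camera adjusted p = 1.39e-41 and 3.52e-49). Cyclin A2 (CCNA2) changed by -5.76 and thymidine kinase (TK1) by -4.74. IFIT1 rose further above the untreated level (3.56), ahead of TPTE2 (2.65), HS3ST4 (2.31), SMIM14 (2.25) and MACROD2 (2.21). GPRC5D, a surface receptor of plasma cells, rose by 2.12.

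Plasma cell identity genes rose in 10 of 21 cases and fell in 1 (13 and 1 adjusted over the list alone, median 0.50, camera adjusted p = 2.30e-04, adjusted p = 0.118 with an estimated correlation). The adhesion receptor CD44 rose by 0.93, IRF4 by 0.79 and PRDM1 by 0.75. Of 27 ER chaperone and folding genes 8 rose (15 adjusted over the list alone, camera adjusted p = 2.36e-05, adjusted p = 0.0519 with an estimated correlation), led by the co-chaperone DNAJB9 (1.15). IRF4 target genes rose in 8 of 20 cases and fell in 3 (11 and 4 adjusted over the list alone, camera adjusted p = 0.0483, adjusted p = 0.202 with an estimated correlation). This call ended with slide as a block (adjusted p = 0.230) and with the replicate number as a block (adjusted p = 0.122). It was kept under only 7 of 22 alternatives, arrays left out in turn included. Lysosome and autophagy genes rose in 14 of 31 cases and fell in 4 (16 and 5 adjusted over the list alone, camera adjusted p = 0.0251, adjusted p = 0.0703 with an estimated correlation), including the autophagy protein WIPI1 (0.89). Of 22 death receptor pathway genes 7 rose and 1 fell (8 and 1 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.0561), except with the replicate number as a block (adjusted p = 0.0437). BCL2 rose by 1.49 and MCL1 by 0.66, while PMAIP1 fell by 4.06 on the log2 scale. BCL2L11, which encodes the pro-apoptotic protein BIM, had a change of 0.11 (limma adjusted p = 0.496), and other probes of it passed the test in the opposite direction. IL13, a cytokine gene not well above background in untreated cells, was at least 3.09-fold higher at 24 h. SLC35D2, a nucleotide sugar transporter not well above background at 24 h, was at least 9.19-fold lower.

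Against untreated cells 3877 genes changed at 24 h in limma's test, 1985 higher and 1892 lower, 1169 of them at least 2-fold. Camera passed 20 of 40 lists, 11 also with an estimated correlation. With slide as a block 5381 genes changed, among them 98.9% of the calls. The G2/M median was -4.41 with the block and -4.43 and -4.59 within slides 1 and 3, and the E2F median -3.06 with the block and -3.08 and -2.99 within them.

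At 36 h the falls were led by TOP2A, the topoisomerase that untangles chromosomes, from 2.37 ± 0.09 to -4.40 ± 0.10 (109-fold; limma adjusted p = 2.52e-14). Behind it were PBK (-6.73), AURKB (-6.55), the cytokinesis protein CEP55 (-6.43) and BIRC5, which encodes survivin (-6.39). All 49 G2/M genes fell, also adjusted over the list alone (median -4.61, camera adjusted p = 1.27e-68). So did 28 of 29 E2F and G1/S regulators, also 28 adjusted over the list alone (median -3.01, camera adjusted p = 1.21e-38). IFIT1 stood 4.07 above untreated cells, the largest rise, followed by TPTE2 (2.99), GUCA1C (2.42), RANBP17 (2.40) and GPRC5D (2.32). Plasma cell identity genes rose in 12 of 21 cases (15 adjusted over the list alone, median 0.53, camera adjusted p = 1.16e-05, adjusted p = 0.0789 with an estimated correlation). CD44 rose by 0.99, CD28 by 0.81, IRF4 by 0.68 and PRDM1 by 0.66. MHC class II genes rose in 9 of 12 cases and fell in 1 (10 and 1 adjusted over the list alone, median 0.54, camera adjusted p = 7.15e-05). HLA-DOB and HLA-DMB rose by 1.54 and 1.05.

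ER chaperone and folding genes rose in 13 of 27 cases (19 adjusted over the list alone, camera adjusted p = 5.91e-06), FKBP2, an ER prolyl isomerase, by 0.75. The quiescence and FOXO-linked list had 12 of 26 genes higher and 1 lower (14 and 2 adjusted over the list alone, camera adjusted p = 6.36e-04), with MXD4, a MYC antagonist, at 1.49. In the ATF4 list 11 of 23 genes fell and 2 rose (11 and 3 adjusted over the list alone, camera adjusted p = 6.57e-04), the cystine transporter SLC7A11 by 2.37 on the log2 scale. Among anti-apoptotic genes 3 of 6 rose, as many adjusted over the list alone, BCL2 2.83-fold, BCL2A1 by 0.76 and MCL1 by 0.78 on the log2 scale. The camera adjusted p of the list was 0.0338 (adjusted p = 0.0789 with an estimated correlation, 0.0764 with slide and 0.0660 with the replicate number as a block). PMAIP1 fell by 4.04 on the log2 scale, from 0.64 ± 0.13 to -3.40 ± 0.41. IRF4 target genes rose in 10 of 20 cases and fell in 3 (11 and 4 adjusted over the list alone). Camera passed the list (adjusted p = 0.0179, adjusted p = 0.126 with an estimated correlation, 0.0762 with slide and 0.0654 with the replicate number as a block). CDK6, a target of the drug and a member of that list, rose by 0.94 (limma adjusted p = 1.63e-04), and the sign of its other probe differed. CDK4 (-0.54), RB1 (-0.20) and MYC (0.27) did not pass the test (adjusted p = 0.121, 0.757 and 0.0566). With the replicate number as a block CDK4 and MYC passed (adjusted p = 8.69e-04 and 0.0466), and with slide as a block CDK4 (adjusted p = 0.00158). The CDK4 level was 2.82 ± 0.33 in untreated cells and lower at 12 h (1.81 ± 0.32) and 24 h (2.05 ± 0.22) than at 36 h (2.28 ± 0.37).

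At 36 h 4023 genes differed from untreated cells in limma's test, 2077 higher and 1946 lower, and 1202 changed at least 2-fold. On the authors' matrix values 2620 were higher and 1263 lower, and the median of all genes shifted by 0.15. Lists passing camera numbered 17 of 40, 11 of them also with an estimated correlation. The count was 5175 with slide as a block, which kept 95.7% of the calls. The G2/M median was -4.64 with that block and -4.64 and -4.54 within slides 1 and 2, and the E2F median -3.01, -2.91 and -3.11. Of the genes higher at 12 h 1008 (80.6%) were also higher at 36 h, and of those lower 1202 (82.0%) were also lower, where independent lists would share 164 and 180. Simulated unchanged groups against the same untreated arrays shared 0 calls, but they made almost no calls, so that value sets no bound. Part of the overlap may come from the shared untreated arrays.

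**Figure D2:**
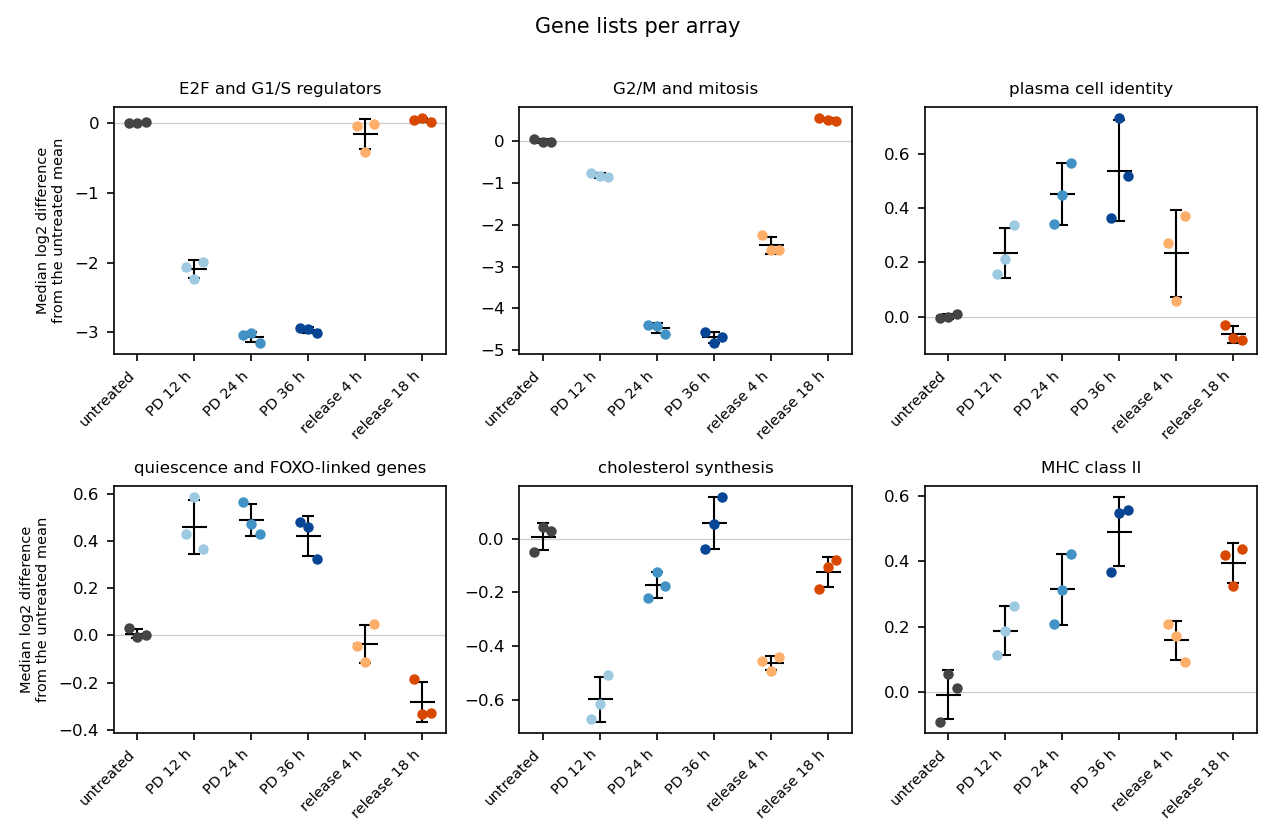
Median log2 difference of 6 gene lists from the untreated mean, for each of the 18 arrays (points; y axis, log2; x axis, group), with the group mean and SD (lines). The E2F list was near its lowest level by 24 h and the G2/M list fell from -0.86 at 12 h to -4.46 at 24 h, and plasma cell identity and MHC class II medians were above 0 in all PD groups.

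Between 12 and 36 h of PD the mitotic genes fell while cholesterol synthesis genes rose. Mitotic genes made up the largest falls: TOP2A (-5.98; limma adjusted p = 1.96e-13), the spindle protein ASPM (-5.74), BIRC5 (-5.67), CEP55 (-5.59) and DLGAP5 (-5.49). Of 49 G2/M genes 46 fell (48 adjusted over the list alone, median -4.01, camera adjusted p = 5.03e-120). Cyclin B2 (CCNB2) changed by -5.11 and CDK1 by -4.95. Replication genes went both ways, 9 higher and 12 lower of 40 (11 and 13 adjusted over the list alone, camera adjusted p = 0.142), with the helicase subunit MCM2 up by 0.72. Cholesterol synthesis genes rose in 15 of 23 cases (20 adjusted over the list alone, median 0.56, camera adjusted p = 1.43e-18). TM7SF2, a sterol reductase, rose by 1.44 and INSIG1 by 1.38.

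IFIT1 had the largest rise (1.94), then SH3PXD2A, an adaptor of invasive protrusions (1.69). MHC class II genes rose in 4 of 12 cases (8 adjusted over the list alone, camera adjusted p = 3.53e-06). Fatty acid synthesis genes rose in 3 of 13 cases and fell in 1, the same numbers adjusted over the list alone (camera adjusted p = 0.0168, adjusted p = 0.0705 with an estimated correlation), and SCD rose by 1.39. MYC, which did not pass against untreated cells at 12 or 36 h, rose by 0.49 (limma adjusted p = 0.00442). Epigenetic regulators fell in 9 of 19 cases, as many adjusted over the list alone (camera adjusted p = 1.42e-04). Proteasome subunits fell in 2 of 31 (1 adjusted over the list alone, camera adjusted p = 0.00239, adjusted p = 0.400 with an estimated correlation). Both lists had a positive median on the authors' matrix values.

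Between 12 and 36 h 1417 genes changed in limma's test, 667 higher and 750 lower, and 360 changed at least 2-fold. With only the 6 arrays compared the count was 655, and on the authors' matrix values, where the median of all genes shifted by 0.25, it was 1552 higher and 362 lower. Camera passed 14 lists of 40, and 6 of these also with an estimated correlation. With slide as a block 1985 genes changed, including 92.4% of the calls. The cholesterol synthesis median was 0.61 with that block and 0.64 and 0.67 within slides 1 and 2, and the G2/M median -4.03, -3.98 and -4.08.

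Within 4 h of release from 24 h of PD the S phase entry genes had risen. UHRF1 went from -3.81 ± 0.17 to 1.65 ± 0.20 (44.0-fold; limma adjusted p = 9.73e-13). The next largest rises were those of DSCC1, which loads the sliding clamp (5.25), the exonuclease EXO1 (5.22), FAM111B (5.11) and the E2F family repressor E2F8 (5.04). Of 29 E2F and G1/S regulators 28 rose, as many adjusted over the list alone (median 2.74, camera adjusted p = 3.35e-51), E2F1 by 3.46. Replication genes rose in 39 of 40 cases, as many adjusted over the list alone (median 2.43, camera adjusted p = 2.62e-62), CDC6 by 3.73. G2/M genes had risen less: 42 of 49 were higher and 1 lower (44 and 2 adjusted over the list alone, median 1.53, camera adjusted p = 1.15e-39), with CDK1 at 3.53 and CCNB1 at 0.93.

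The largest falls were those of CCNG2, a cyclin G gene induced in quiescence (-2.58; limma adjusted p = 1.35e-07), the cholesterol exporter ABCA1 (-1.89), PDZRN4 (-1.74), the ion channel TRPM8 (-1.68) and the deacetylase HDAC9 (-1.66). Quiescence and FOXO-linked genes fell in 16 of 26 cases and rose in 1 (17 and 1 adjusted over the list alone, median -0.56, camera adjusted p = 1.50e-08). IRF4 fell by 0.96 and PRDM1 by 0.47 on the log2 scale (limma adjusted p = 2.78e-05 and 0.00782), and with slide as a block PRDM1 no longer passed (adjusted p = 0.237). The plasma cell list had 4 of 21 genes lower, as many adjusted over the list alone (camera adjusted p = 0.0260, adjusted p = 0.400 with an estimated correlation and 0.124 with slide as a block). TNFSF10, which encodes the death ligand TRAIL, fell by 1.55 on the log2 scale, and PMAIP1 rose by 2.87. MYC target and ribosome biogenesis genes rose in 14 of 35 cases (15 adjusted over the list alone, median 0.31, camera adjusted p = 8.83e-07, adjusted p = 0.0882 with an estimated correlation). The nucleolar proteins NOP56 and NOLC1 rose by 0.70 and 0.67. Interferon response genes fell in 12 of 31 cases and rose in 2, the same numbers adjusted over the list alone (camera adjusted p = 0.00192, adjusted p = 0.153 with an estimated correlation).

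At 4 h of release 2833 genes differed from 24 h of PD in limma's test, 1454 higher and 1379 lower. On the authors' matrix values 1174 were higher and 676 lower, and with only the 6 arrays compared 1421 differed. Camera passed 14 of 40 lists, 8 also with an estimated correlation. These groups share no slide, and slide as a block compares them through the other groups. With that block 2524 genes changed, including 70.2% of the calls, and the E2F and G2/M medians were 2.88 and 1.69. Within scan day 1 the 2 medians were 2.67 and 1.55 and within scan day 2 they were 2.77 and 1.51.

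By 18 h of release the mitotic genes had risen too. SPC25 rose from -4.77 ± 0.10 to 2.87 ± 0.09 (200-fold; limma adjusted p = 8.44e-15). After it came the cohesin acetyltransferase ESCO2 (7.29), PBK (7.04) and AURKB (7.02). All 49 G2/M genes rose, also adjusted over the list alone (median 5.09, camera adjusted p = 4.65e-60). So did 28 of 29 E2F and G1/S regulators (28 higher and 1 lower adjusted over the list alone, median 3.11, camera adjusted p = 4.95e-32). IFIT1 had the largest fall, from 1.09 ± 0.04 to -3.29 ± 0.21, then SMIM14 (-3.18), the neuronal serpin SERPINI1 (-2.96) and the histone demethylase KDM7A (-2.89). Plasma cell identity genes fell in 12 of 21 cases and rose in 2 (13 and 2 adjusted over the list alone, median -0.48, camera adjusted p = 7.57e-04, adjusted p = 0.198 with an estimated correlation). CD44 changed by -1.62, IRF4 by -1.52 and PRDM1 by -1.36.

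ER chaperone and folding genes fell in 22 of 27 cases (24 adjusted over the list alone, median -0.63, camera adjusted p = 8.09e-08), the ER chaperone BiP (HSPA5) by 0.98 on the log2 scale. IRF4 target genes fell in 12 of 20 cases and rose in 1, the same numbers adjusted over the list alone (camera adjusted p = 0.00161, adjusted p = 0.0553 with an estimated correlation). Quiescence and FOXO-linked genes fell in 17 of 26 cases and rose in 1 (18 and 1 adjusted over the list alone, camera adjusted p = 8.57e-07). Of the 6 anti-apoptotic genes 3 fell (4 adjusted over the list alone), with BCL2 at -1.91, BCL2A1 at -1.01 and MCL1 at -1.02 (camera adjusted p = 0.0151, adjusted p = 0.0553 with an estimated correlation and 0.0748 with slide as a block). PMAIP1 rose by 3.64. Death receptor pathway genes fell in 8 of 22 cases, with the adaptor TRADD at -1.19, and rose in 2 (10 and 2 adjusted over the list alone). The camera adjusted p was 0.0492 (adjusted p = 0.320 with an estimated correlation, 0.155 with slide and 0.0519 with the replicate number as a block). Ribosomal protein genes fell in 8 of 37 cases, as many adjusted over the list alone (camera adjusted p = 9.51e-05, adjusted p = 0.621 with an estimated correlation). Oxidative phosphorylation genes fell in 10 of 34, as many adjusted over the list alone (camera adjusted p = 0.0200, adjusted p = 0.621 with an estimated correlation and 0.155 with slide as a block).

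Compared with 24 h of PD 5038 genes changed by 18 h of release in limma's test, 2286 higher and 2752 lower, and 1711 at least 2-fold. The split was 3264 higher and 1962 lower without the arrays of slide 4, 2344 and 4044 without those of slide 5, and 2150 and 1811 on the authors' matrix values. Camera passed 18 of 40 lists, 9 also with an estimated correlation. With slide as a block 4516 genes changed, including 73.1% of the calls. The E2F and G2/M medians were 3.04 and 5.05 with the block, 3.05 and 5.07 within scan day 1, and 3.11 and 5.05 within scan day 2.

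**Figure D3:**
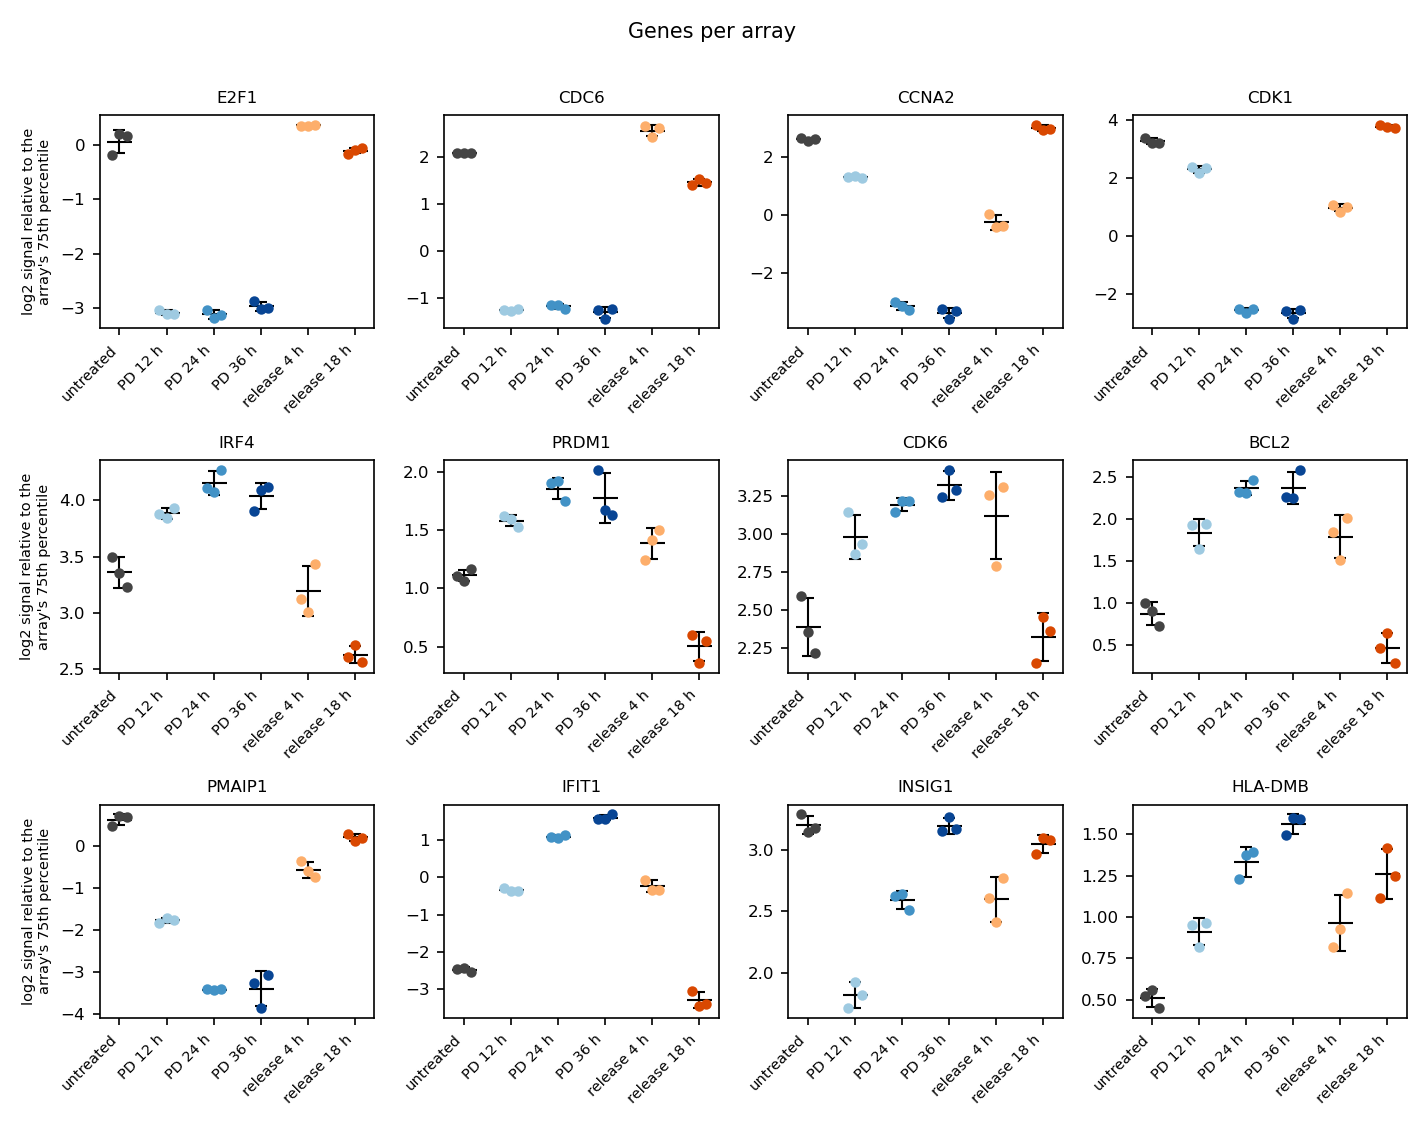
Levels of 12 genes on each array (points; y axis, log2 signal relative to the array's 75th percentile; x axis, group) with the group mean and SD (lines). E2F1 and CDC6 were back near or above the untreated level at 4 h of release, CCNA2 and CDK1 only at 18 h; IFIT1 stood at -2.47 in untreated cells, 1.60 at 36 h and -3.29 at 18 h of release.

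How far the changes of the arrest were reversed was measured on arrays that the 2 comparisons do not share. Of the 4023 genes changed at 36 h, 3143 (78.1%; 95% exact binomial interval 76.8 to 79.4%) changed the opposite way between 24 h of PD and 18 h of release. That was 1568 of the 2077 higher genes, such as IFIT1 (4.07 and then -4.38), and 1575 of the 1946 lower genes, such as TOP2A (-6.76 and then 6.89); independent lists would share 361 and 281. Another 16 higher and 19 lower genes moved on in the same direction. Across the 4023 genes, which are not independent replicates, the 2 changes correlated at -0.95 with a slope of -1.03. With slide as a block the share was 61.4%, and on the authors' matrix values 65.4%. Without 1 array at a time it ran from 73.6 to 84.7%, beyond the interval, which takes genes as independent.

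**Figure D4:**
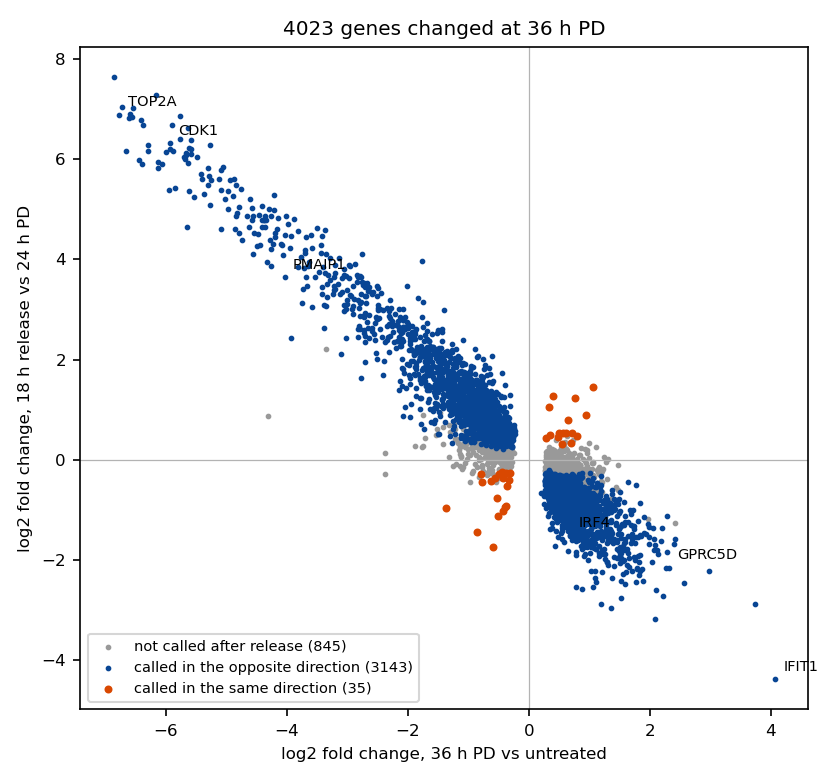
Log2 change of the 4023 genes changed at 36 h of PD against untreated cells (x axis) and between 24 h of PD and 18 h of release (y axis); each point is a gene. Blue marks the 3143 genes called in the opposite direction after release and orange the 35 called in the same direction.

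After 18 h of release a smaller set of genes differed from untreated cells. Of these 701 genes 228 had not been called at 24 h of PD, and 349 of those called then had passed the untreated level. SCUBE2, a secreted and membrane-bound protein, had the largest rise (-3.81 ± 1.90 against -6.94 ± 0.29; limma adjusted p = 0.0391). Its adjusted p was 0.0867, 0.115 and 0.140 without untreated replicate 1, 2 or 3, and 0.169 and 0.138 without release replicate 2 or 3. The fructose transporter SLC2A5 was higher by 2.48, CXCL10, an interferon-inducible chemokine, by 2.30 (2.85 ± 0.13 against 0.55 ± 0.09; limma adjusted p = 1.16e-07), and the nucleotide receptor P2RY6 by 2.02. FOS, an immediate early transcription factor, was lower (-2.86), as were the galectin LGALS1 (-1.73), LIMS3 (-1.59) and the neutrophil calgranulin S100A9 (-1.57). Of 49 G2/M genes 16 were higher than in untreated cells (30 adjusted over the list alone, median 0.50, camera adjusted p = 5.07e-24). NDC80 of the kinetochore was higher by 0.97, and the list median was 0.59 with slide as a block and 0.48 and 0.53 within scan days 1 and 2.

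IRF4 was at 2.63 ± 0.08 after release and 3.36 ± 0.14 in untreated cells (-0.73; limma adjusted p = 0.00219), and PRDM1 at 0.50 ± 0.13 and 1.11 ± 0.05 (-0.61; adjusted p = 0.00605). With slide as a block the 2 differences were -0.61 and -0.42 and did not pass (adjusted p = 0.0897 and 0.181). IRF4 differed by -0.89 and -0.65 and PRDM1 by -0.51 and -0.66 within scan days 1 and 2. The calls also ended with only the 6 arrays compared, that of IRF4 with the mean of its probes, and that of PRDM1 without slide 4 and on the authors' matrix values. MHC class II genes were higher in 6 of 12 cases, as many adjusted over the list alone (median 0.34, camera adjusted p = 3.71e-09), HLA-DQB1 by 0.77 and HLA-DMB by 0.75. The list median was 0.37 with slide as a block and 0.40 and 0.31 within scan days 1 and 2. ATF4 response genes were lower in 7 of 23 cases (9 lower and 1 higher adjusted over the list alone, camera adjusted p = 2.57e-06), with SLC7A11 at -1.41. Quiescence and FOXO-linked genes were lower in 6 of 26 cases (9 adjusted over the list alone, camera adjusted p = 1.74e-06), with TXNIP, a thioredoxin inhibitor, at -1.04. NF-kB target genes were higher in 5 of 22 cases and lower in 1 (7 and 1 adjusted over the list alone, camera adjusted p = 6.71e-04, adjusted p = 0.0530 with an estimated correlation), lymphotoxin beta (LTB) by 0.87.

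Between 18 h of release and untreated cells 701 genes differed in limma's test, 356 higher and 345 lower, and 2382 had an unadjusted p under 0.05. The split was 149 and 218 with median scaling and 155 and 84 on the authors' matrix values. With only the 6 arrays compared the count was 8, with the replicate number as a block 1388 and with slide as a block 552, which kept 43.7% of the calls. Without untreated replicate 1, 2 or 3 it was 434, 340 and 325, without release replicate 2 or 3 it was 399 and 378. Without the arrays of slide 4 it was 1243, 1052 higher and 191 lower, and without those of slide 5 it was 1154, 434 higher and 720 lower. Camera passed 11 of 40 lists, 4 also with an estimated correlation.

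Of the 3877 genes changed at 24 h, 124 (3.20%; 95% exact binomial interval 2.67 to 3.80%) still differed from untreated cells in the same direction at 18 h of release, 71 higher and 53 lower. Here independent lists would share 44.7 and 41.3, and simulated unchanged groups, with at most 1 call each, shared 0, which sets no bound. Part of these 124 may come from the shared untreated arrays. HLA-DMB was one of them (0.82 at 24 h and 0.75 after release), as was SLC7A11 (-1.55 and -1.41). The share was 0.0451% with only the 6 arrays compared, 2.10% with slide as a block, 4.82% with the replicate number as a block. It was 2.10, 2.02, 2.01 and 1.98% without untreated replicate 2 or 3 or release replicate 2 or 3. These values lie below the interval, which takes genes as independent. Across all genes the 2 changes had a covariance of -0.0454, against 0.0490 in the simulated groups. A further 349 of the genes changed at 24 h had passed the untreated level: 177 of the higher genes, IRF4 and PRDM1 among them, were lower than in untreated cells and 172 of the lower genes were higher. Independent lists would share 43.3 and 42.6. All 349 kept their sign with slide as a block (median signed change 0.55, against 0.58 without the block), and 156 were called. They had been picked on these same arrays, which favours a kept sign.

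Some lists passed in no comparison, at the lowest camera adjusted p given here. These were cyclin D, CDK4/6 and RB pathway genes (0.145), mature B cell identity (0.177), pro-apoptotic BCL2 family (0.0900), p53 targets (0.213), MHC class I (0.148), glycolysis (0.311) and hypoxia response (0.438). Markers of other cell types passed in none either: T and NK cells 0.546, myeloid cells 0.504, erythroid cells and megakaryocytes 0.258, stromal and endothelial cells 0.345, and epithelial cells 0.401. Single members of these lists changed, as with CDKN1A, the p21 gene (-1.13 at 12 h), TP53I3 (1.36 at 36 h), the chemokine CCL5 (1.46 at 36 h) and fibronectin (FN1, -2.42 at 36 h).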

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

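Of the tests here, those of slide as a block for genes past the untreated level, of slide and time in culture for the cholesterol genes, and both on IFIT1 were chosen only after the result was seen.

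The 36 h and 12 h groups of PD were compared by limma on the difference itself, and 1417 genes differed. No untreated group was taken at a later time. For these genes and lists a part played by time in culture therefore cannot be told apart from a change in the effect of PD. For the G2/M list the release arrays argue against time in culture alone. After 24 h of PD and then 18 h of release its median was 5.09 above 24 h of PD and 0.50 above untreated cells. This holds unless release itself reset such an effect, which was not tested. G2/M genes differed most as a list (median -4.01), followed by homologous recombination and Fanconi genes (-0.59), E2F and G1/S regulators (-0.44), proteasome subunits (-0.16), epigenetic regulators (-0.11) and nuclear envelope genes (-0.050). Cholesterol synthesis genes (0.56), MHC class II (0.34), IRF4 targets (0.23), ER chaperones (0.22), plasma cell identity (0.19), fatty acid synthesis (0.19), ribosomal proteins (0.15) and MYC targets (0.12) differed upwards. Calls lost with an estimated correlation were those of nuclear envelope (adjusted p = 0.264), IRF4 targets (0.242), ER chaperones (0.275), plasma cell identity (0.299), ribosomal proteins (0.714) and MYC targets (0.366), with fatty acid and proteasome genes as in the report. The nuclear envelope median changed its sign under 2 alternatives, and those of proteasome and epigenetic genes under 1 each. Among the largest rises were IFIT1 (1.94), SH3PXD2A (1.69), TG (1.60), PRXL2B (1.52), GNG7 (1.48), NPPC (1.47) and TPTE2 (1.46), and the largest falls TOP2A (-5.98), ASPM (-5.74), BIRC5 (-5.67), CEP55 (-5.59), DLGAP5 (-5.49), CENPF (-5.38), PBK (-5.37) and AURKB (-5.24). Among the core genes MKI67 (-5.54), CDK1 (-4.95), CCNA2 (-4.71), CCNB1 (-4.34), PLK1 (-4.01), TK1 (-3.95), RRM2 (-3.78), CDC20 (-3.47), AURKA (-3.25), PMAIP1 (-1.63) and TYMS (-1.46) fell from 12 to 36 h, and MCM2 (0.72), BCL2 (0.53) and MYC (0.49) rose. BCL2 was no longer called without replicate 1, 2 or 3 of 12 h (adjusted p = 0.0593, 0.164 and 0.0624) or replicate 2 or 3 of 36 h (adjusted p = 0.0537 and 0.148).

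Probes whose accession has no gene name were left out of the comparisons. Of 14374 such accessions 2775 (19.3%) changed in limma's test at 36 h of PD against untreated cells, beside 25.4% of the named genes. Their log2 changes ran from -7.20 to 4.51. Whether they are further probes of named genes was not tested.

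Genes that passed the untreated level by 18 h of release (349 of those changed at 24 h) were measured on release arrays of slides 4 and 5 only, which hold no untreated array. Genes picked on replicates 2 and 3, whose release arrays lie on slide 4, had a median signed difference of 0.533 in replicate 1 (297 genes), and genes picked on replicate 1, on slide 5, had 0.591 in the other replicates (243 genes), which argues against 1 dim or bright slide as the whole cause. These sets were picked by size (at least 1 on the log2 scale at 24 h and 0.5 the other way after release). The size rule was taken because picking by adjusted p gave no usable set, so it was chosen after that attempt. The sets were uneven in direction (202 and 95 genes, and 197 and 46), while the 349 were 172 and 177. The 2 medians therefore rest mostly on genes of 1 direction. The sets hold neither IRF4 nor PRDM1 and are not the 349 genes. With slide as a block all changes of this comparison had a correlation of 0.677 with those without it. The median signed change of the 349 was then 0.552 (median standard error 0.14) against 0.58 (0.11), all with the same sign. The 349 had been called on these same arrays, which favours a kept sign, and slide 5 holds release arrays only. The block therefore cannot decide on signal that slides 4 and 5 share. The block ended the calls of 193, IRF4 and PRDM1 among them. Their median change fell from 0.50 to 0.44 and its standard error rose from 0.11 to 0.14. Time in culture and a lasting effect of the release, both untested here, stay open for all 349. So does signal that slides 4 and 5 share, and other explanations were not tested. Of 49 G2/M genes 16 had passed the untreated level upwards and 0 downwards, more than in any other list.

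Cholesterol synthesis genes were low at 12 h (median -0.60) and back by 36 h (0.06). Within the slides that hold both groups the lowest median of 36 h minus 12 h was 0.636, which argues against slide and scan day. An offset per array cancels from a median taken relative to all genes, so only quantile (0.527) and normexp (0.544) could move that value. The list median itself ran from 0.540 to 0.801 over the 6 scalings, which argues against the choice among these scalings as the cause. The study held 0 untreated groups taken at a later time, so time in culture cannot be told apart from time with PD.

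IFIT1 rose by 2.13, 3.56 and 4.07 at 12, 24 and 36 h. The lowest difference at 36 h within a slide that holds both groups was 4.02, which argues against slide and scan day. Of the other 30 interferon response genes 10% rose between 12 and 36 h, under the bound of 25% set after the list had been seen, which argues against the interferon response as a whole rising on as IFIT1 did. After 24 h of PD and then 18 h of release IFIT1 stood at -3.29, against -2.47 in untreated cells and 1.60 at 36 h of PD. That argues against time in culture alone for IFIT1, unless release itself reset such an effect, which was not tested. No other biological explanation was tested, and a part played by time in culture cannot be told apart from time with PD.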

How the results depend on the processing

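Scan day as a block, the arrays without slide 4 or 5, normexp on the median signals and the probes without a gene name were chosen only after the data were seen; normexp on the mean signals had been planned and was not run, as the files hold no mean signals. Of 20648 values of the called among the genes named by the rule, under alternatives, 19396 kept direction and call, 1249 kept the direction only and 3 turned: RPL30 at 36 h of PD (-0.12 with normexp), FCN1 at 4 h of release (0.029 with the mean of all probes) and BCL2L11 at 18 h of release against 24 h of PD (0.12 with the mean of all probes). Of these genes' 901 calls 657 were kept under each alternative that tested the gene. The limit to probes well above background on all arrays left 826 calls to test. The rule picks genes largely by size or p on these same arrays, which favours a kept call. Of all 701 calls between 18 h of release and untreated cells 1.14% were kept with only the 6 arrays compared. It was 33.4% on the authors' matrix, 43.7% with slide as a fixed block, 46.6% with median scaling and 100% with the replicate number as a block. The cause of the changes below was not tested, except where a size limit makes the count smaller, or more probes make it larger. Fewer arrays cannot be taken as the cause of the smaller counts with only the arrays compared. That setting raised 2717 to 2947 at 12 h and 3877 to 4432 at 24 h of PD. It lowered the count in every comparison with 36 h or release arrays. The median SD of a gene was 0.211, 0.272 and 0.234 at 36 h of PD and 4 and 18 h of release. It was 0.134 to 0.158 in the other groups. Whether this spread lowered the counts was not tested.

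With median scaling 367 genes differed between 18 h of release and untreated cells, and with the authors' matrix 239 (4 h of release against 24 h of PD 1850). With only the 6 arrays compared the counts were 655 between 36 and 12 h of PD, 1421 at 4 h of release and 8 between 18 h of release and untreated cells. Slide as a fixed block gave 4195 and as a random block 4342 at 12 h, and the random block 2354 between 36 and 12 h. Scan day as a block gave 2389 between 36 and 12 h and 1527 between 18 h of release and untreated cells, and leaving out slide 4 or slide 5 gave 1243 and 1154 there, 1052 and 434 of them higher. With unnamed probes 6008, 6577 and 8099 changed at 24 h, at 36 h and at 18 h of release against 24 h of PD. At least 2-fold were 644, 1169, 1202, 360, 663, 1711 and 83 genes in the 7 comparisons, in the report's order.

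With an estimated correlation 12, 11, 11, 6, 8, 9 and 4 lists passed, in the same order, and with fry 28 at 36 h, 22 between 36 and 12 h, 22 at 4 h and 28 at 18 h of release against 24 h of PD.

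The replicate number as a block raised 701 to 1388 between 18 h of release and untreated cells. It moved no other paired count by over 1.5 times, though all of them rose. The splits were 1915 higher and 1919 lower at 12 h, 2733 and 2305 at 24 h and 2792 and 2483 at 36 h of PD. Against 24 h of PD they were 1865 and 2065 at 4 h and 2782 and 3438 at 18 h of release. The block changed no other call described in the text than those given beside their results. Between 36 and 12 h, where the pairing check failed (r -0.04 to 0.61), the block gave 2246 genes. With it 76.3% of the 36 h calls moved back by 18 h of release, and 4.82% of the 24 h calls stayed changed.

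The share of 36 h calls that moved back (78.1%) was 65.4% on the authors' matrix, 76.3% with only the arrays compared, 61.4% with slide as a fixed and 69.4% as a random block, 76.4% with scan day as a block, 70.0 and 73.8% without slides 4 and 5, and 88.0% for the 12 h calls. The share of 24 h calls that stayed changed (3.20%) was 1.90% with median scaling, 1.58% on the authors' matrix, 2.56% with normexp, 3.85% with only probes well above background on all arrays, 0.0451% with only the arrays compared, 2.10% with slide and 5.35% with scan day as a block, and 4.06% without slide 4.

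Without 1 array at a time the counts ran from 2071 to 2425, 3192 to 3571, 3274 to 3873, 953 to 1388, 2133 to 2686, 4260 to 5331 and 325 to 735, and the lists from 19 to 22, 18 to 22, 16 to 18, 10 to 15, 11 to 16, 15 to 18 and 9 to 16. The 2 shares ran from 73.6 to 84.7% and from 1.98 to 3.24%. Arrays of slide 4 had 70.9 to 86.6% of probes well above background, so dim genes of the 36 h and release groups are the least certain.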

Other observations

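The test of the order of the gene lists was chosen only after the result was seen.

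Heat shock genes fell at 24 h of PD in 7 of 16 cases (10 adjusted over the list alone, camera adjusted p = 1.01e-04, adjusted p = 0.0543 with an estimated correlation), with the chaperone HSP90AA1 at -1.33 and the co-chaperone DNAJB1 at -1.47. At 18 h of release 8 rose against 24 h of PD (9 adjusted over the list alone, camera adjusted p = 1.45e-04, adjusted p = 0.0670 with an estimated correlation), HSP90AA1 by 1.54. Immediate early genes fell at 12 h in 6 of 18 cases and rose in 1 (8 and 1 adjusted over the list alone, camera adjusted p = 0.00646, adjusted p = 0.168 with an estimated correlation), with the phosphatase DUSP1 at -1.37 and FOS at -3.67. Glucocorticoid-responsive genes fell at 12 h in 4 of 15 cases, as many adjusted over the list alone (camera adjusted p = 0.0237, adjusted p = 0.120 with an estimated correlation), among them CXCR4, a chemokine receptor (-0.98), and FKBP5, a steroid receptor co-chaperone (-1.47). Replication-dependent histone genes were higher at 18 h of release than in untreated cells in 2 of 31 cases (8 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0106, adjusted p = 0.566 with an estimated correlation), the linker histone H1-2 by 0.77.

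Ribosomal protein genes at 4 h of release had 0 members lower and 0 higher, though camera's adjusted p was 0.0473 (adjusted p = 0.815 with an estimated correlation, 0.309 with slide and 0.0798 with the replicate number as a block), and the list median changed its sign under 2 alternatives. IRF4 target genes, lower at 18 h of release than in untreated cells (camera adjusted p = 7.74e-04, adjusted p = 0.0657 with an estimated correlation), did not pass with slide as a block (adjusted p = 0.0717). At 18 h of release against 24 h of PD the interferon list (camera adjusted p = 0.0357, adjusted p = 0.320 with an estimated correlation) did not pass with slide or the replicate number as a block (adjusted p = 0.0629 and 0.0531), nor the lysosome list (camera adjusted p = 0.0366, adjusted p = 0.106 with an estimated correlation) with slide as a block (adjusted p = 0.0848).

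The hypothesis that genes leave and rejoin the cycle in the same order, G1/S before G2/M, was tested on the share of the 36 h fall reached at 12 h and the share of the 18 h release rise reached at 4 h, which share no array. For 67 G1/S or replication genes the medians were 86.9 and 95.9%, and for 49 G2/M genes 16.9 and 30.8%. Across the 116 genes the shares had a Spearman correlation of 0.891 and within the lists of 0.797 and 0.349. The genes of a list are regulated together, so they are not independent replicates in any of these values.

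Splits of the 6 arrays of each comparison into other groups of 3 called at most 0 genes, and 1 of 10 splits, the real one, reached its own count in each comparison: 2947, 4432, 3113, 655, 1421, 4275 and 8 genes with only these arrays, in the report's order. The 10 splits are too few for a share under 0.05.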
